A study of Zea mays with 9 samples.

How the data were processed

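Root tips of wild-type maize seedlings (inbred line B73) were measured in 9 samples. Per the labels' protocols, seedlings grew on germination paper at 26 °C, with 12 hours of light per day for 3 samples and 16 hours for 6. Cell walls were digested, the protoplasts were strained, and libraries were made with the 10x Chromium Single Cell 3' chemistry, kit V2 for the first 3 samples and V2 and V3 for the other six. Per the submitters' processing notes, bcl2fastq, Cell Ranger and Seurat were used. Their versions, the genome build, the filters on cells and any removal of doublets were not given in the sources used here.

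The deposited expression matrix holds natural log values, ln(1 + 10000 × UMIs of the gene / UMIs of the cell), for 28759 genes in 14733 cells; this formula was worked out from the values and is not stated by the authors. With the UMI total per cell that the authors deposited as counts, all 82495625 non-zero values gave whole UMIs within 1e-06, and the UMIs of all 14733 cells summed to the deposited totals. The authors also deposited a table of raw UMI counts for 4324 of these cells, from 3 libraries, with 27533 gene rows. It held 100% of the matrix's UMIs for Maize_Cell_2 and Maize_Cell_3 and 74.9% for Maize_Cell_1. The deposited annotation gives each cell's library and a cluster number from a clustering of integrated data, per the file headers, and no cell type names. The clusters were used as deposited.

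The names of the 9 libraries could not be tied to the 9 samples by any label, so each library served as a replicate of the 1 group without a number, and light regime and kit could not be assigned to libraries. Nothing in the labels says that samples came from separate plantings, so p-values measure the spread between these libraries, which may be technical. For each gene that spread was estimated over all tested clusters together, so it can be smaller than the spread within a given cluster. The 3 Maize_Cell libraries and the other 6 did not use the same set of gene names: 240 genes with at least 200 UMIs had none in the Maize_Cell libraries, and 93 had UMIs in these alone. Genes with UMIs in 1 of these sets only were left out of all tests.

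Gene names came from 182 rows of the counts table that carry a symbol. A symbol was paired with an identifier where both had the same UMIs in each of 1925 cells and at least 20 UMIs, which named 151 genes. The reference table given held none of the other nuclear identifiers, so all other nuclear genes were tested without a name, and no chromosome positions are printed. It matched all 186 organelle locus tags. Of the 18 gene lists fixed before the data were examined, S phase (23 members tested), aquaporins (16 of 18) and ribosomal proteins (8) had several named members. The ground tissue regulators (SCR), the list for protoplasting, wounding and heat stress (GST4) and the cytokinin and gibberellin list (D8) had 1 each. Organelle-encoded genes were summed as shares of UMIs. The lists for endodermis Casparian strip, epidermis and root hair, root cap, quiescent centre and initials, xylem and secondary wall, phloem, procambium with pericycle and stele, G2 and mitosis, cell wall loosening, class III peroxidases, and auxin transport and response had no named member. Identifiers recalled for further list members were not used, since no table given pairs them with a name.

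Cells are not replicates, so values were averaged per library and cluster. A mean needed at least 10 cells and 10000 UMIs, and a cluster at least 3 such libraries, a number set after the cells per cluster had been seen. This kept 20 clusters and 165 of 180 possible means and left out clusters 20 and 21, so the highest and lowest means named in the text are those among the 20 tested clusters. The planned test assumed raw counts for all libraries; because the matrix holds log values, the fallback planned for that case was used. The deposited values were rescaled to log2(1 + UMIs per 10000), a pseudocount of 1, averaged over cells, and fitted with limma 3.58.1 in R 4.3.3. The model had cluster and library as terms, the library being a block because clusters of 1 library share its root tips, with a mean-variance trend and two-sided tests. Each cluster was compared with the mean of the other clusters, and p-values were adjusted by Benjamini-Hochberg within each cluster. Genes needed a mean of at least 0.05 UMIs per 10000 over the means. Differences on this scale understate the change of low genes. Levels in the text are means over libraries of UMIs per 10000, with the SD between libraries; the level in the other clusters is taken in the same libraries.

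On simulated data, in which cluster labels were shuffled within libraries and 200 genes were changed in cluster 4 among 12776, limma recovered 97% of the 100 genes changed 2 times and 100% of the 100 genes changed 4 times. Their median log2 differences were 0.52 and 0.79, and 0 of 12576 unchanged genes were called in cluster 4. In the other clusters' contrasts 3 higher calls were made for the changed genes. The changed genes had at least 1 UMI per 10000 and were made higher in cluster 4, which had 9 libraries. Recovery of genes at lower levels, of lower genes and in clusters with fewer libraries was not simulated. Shuffled clusters also hold none of the variation between libraries in how a real cluster differs from the others. Recovery in the real clusters can therefore be lower, and false calls more frequent, than in this simulation. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 60 list and cluster tests. Labels were also shuffled 99 times within libraries and the fits repeated, to count how often shuffled clusters gave as many calls. These shuffles gave 218 to 1991 gene and cluster pairs at the threshold, with a median of 558 of 255520. The ribosomal list was also compared with all genes per library, as the median log2 fold on summed UMIs for genes with at least 5 UMIs expected in the cluster.

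Named genes followed a rule fixed before the data were examined. For each cluster it takes the 3 named genes with the highest log2 difference of at least 1, an adjusted p below 0.05, at least 0.5 UMIs per 10000 in the cluster, and the same direction in every library. It adds SCR and the 2 most abundant members of each list. The rule gave 37 gene and cluster pairs from 20 genes. The planned contrasts of cortex with endodermis, stele with ground tissue and epidermis with ground tissue need cell type names and were not run.

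Alternatives were the pseudocount, no filter, no replicate block, each library left out, at least 30 cells per mean, the 299 cells above the 98th percentile of their library's UMIs left out as possible doublets, and edgeR 4.0.16 with DESeq2 size factors and DESeq2 1.42.0 on UMIs recovered from the matrix. Further ones, chosen after seeing the data, were edgeR with TMM on recovered UMIs and on the deposited counts of 3 libraries, each name family of libraries alone, the lists without Maize_Cell_1, SCR without each library, and genes and lists with cells reassigned to clusters. In the last, each cell's UMIs were split at random into equal parts. One part, using 2000 variable genes without a symbol, assigned the cell to the closest cluster profile from the other libraries, and the other part gave the values; 64.9% of cells returned to their cluster. Counting, averaging and plotting used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Intervals of summed UMIs are exact Poisson intervals at 95% and cover counting error only.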

Results

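Single cells of the maize root meristem were profiled by droplet-based RNA sequencing. Tips of 3 to 4 mm were taken from roots of wild-type seedlings of the inbred line B73 at 7 days after germination, and their cells were released as protoplasts, that is, cells whose walls had been digested with enzymes. The 9 samples formed 1 group. The series concerns the ground tissue, the cortex and endodermis of the root, and with 1 group the comparisons its design gives are between the cell clusters that the authors deposited. The deposited annotation numbered these clusters 0 to 21 and gave them no cell type names, so they are called by number here. It held 14733 cells in 22 clusters and named 9 libraries, which no label ties to a sample.

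The 9 libraries together held 475524072 UMIs (unique molecular identifiers, each counting 1 captured transcript). Library Meri_2 was the largest, with 2763 cells and 96618472 UMIs, and Maize_Cell_3 had the fewest UMIs, 9906516 from 860 cells. Median UMIs per cell were 14814 in Maize_Cell_1, 26344 in Maize_Cell_2 and 8347 in Maize_Cell_3. They were 31928.5, 30708, 58019.5 and 37820 in Meri_1 to Meri_4, and 26442 and 45528 in Upper_1 and Upper_2. Cluster medians ran from 13419.5 UMIs per cell in cluster 17 to 53159.5 in cluster 5.

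The clusters differed in size and in how evenly the libraries filled them. Cluster 0 was the largest, with 10.9% ± 3.07 of a library's cells (SD, n = 9), followed by cluster 1 with 8.87% ± 3.83 and cluster 2 with 8.10% ± 3.96. Cluster 7 held 4.74% ± 8.14, a spread set by library Maize_Cell_1, where it held 26.1% of the cells against 0.779% to 5.45% in the other libraries. Without that library its mean share was 2.06%. Shares also moved with the library names. Cluster 12 held 7.44% to 10.6% of the cells in the 3 Maize_Cell libraries, 1.63% to 2.86% in the Meri libraries and 0.533% to 0.591% in the Upper libraries. Cluster 3 ran the other way, with 0.125% to 1.98%, 6.01% to 8.44% and 12.8% to 15.8% in the same order. These name families are not groups of the study, and no test was run between them. The samples also split into 3 and 6 by light regime and kit, as the libraries do into 3 Maize_Cell and 6 others. No label ties the 2 splits together, so a part of light or kit in these shares could not be told apart.

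**Figure D1:**
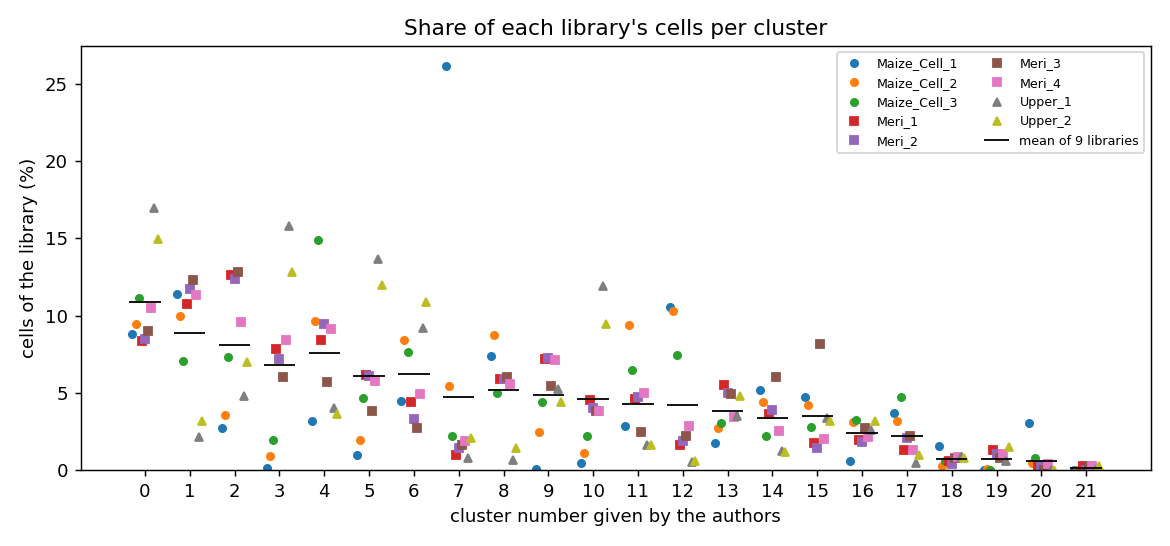
Percent of each library's cells (vertical axis) in each of the 22 clusters (horizontal axis), with 1 point per library and a line at the mean of the 9 libraries. In cluster 7 the point of Maize_Cell_1 sits at 26.1%, and the other libraries lie between 0.779% and 5.45%.

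Levels of many genes differed between clusters, by amounts that depended on the scale. Each of 12776 genes was compared between each of 20 clusters and the mean of the other clusters, within libraries, by limma on the mean log2(1 + UMIs per 10000). Of 255520 gene and cluster pairs, 50708 were higher and 57259 were lower at an adjusted p of 0.05 (Benjamini-Hochberg). Of these, 1256 were higher and 784 lower by at least 1 on the log2 scale. These counts depended on the pseudocount of 1, and were 7520 and 5670 at a pseudocount of 0.1 and 62 and 29 at 10. At the pseudocount of 1, cluster 18 had the most such genes, 288 higher and 144 lower, cluster 13 had 81 and 160, and cluster 19 had 124 and 129. Among all calls, cluster 13 had 2016 higher and 5525 lower at a median of 19572 UMIs per cell, and cluster 19 had 1883 and 4782 at 15849. Cluster 5 had 2069 and 1368 at 53159.5, and cluster 11 had 2853 and 1321 at 42419. Clusters 7 and 3 went the other way, with 3780 and 3123 at 13831.5 and 2666 and 3517 at 39614. Whether depth set the direction of calls was not tested. Higher pairs made up 47.0% of the calls, whereas edgeR's quasi-likelihood test on UMIs recovered from the same values called 94945 pairs higher and 63534 lower, 59.9% higher. On that test's fold scale 42010 were higher and 29913 lower by at least 1, and with the deposited counts of 3 libraries 23815 and 11311. Within the Maize_Cell libraries alone 18789 pairs were higher and 14987 lower, within the Meri libraries 62150 and 81072, and within the Upper libraries 36006 and 38233. The authors built the clusters from the expression of these same cells, so the tests describe how the clusters differ and are no independent evidence that the clusters exist.

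Histone transcripts set cluster 14 apart. The S phase list held 23 tested genes, which were copies of histone H4 (H4C7), copies of histone H3 (H3C2) and PCNA, the sliding clamp of DNA replication. All 23 were higher in cluster 14, with a median log2 difference of 2.05, and all 23 also passed adjusted over the list alone. The list test (camera) gave an adjusted p of 1.0e-147 with the preset correlation and an adjusted p of 9.1e-11 with an estimated correlation. H4C7.2 (Zm00001d002543) averaged 31.5 ± 19.7 UMIs per 10000 in cluster 14 (SD, n = 9 libraries) and 2.93 ± 2.42 in the other clusters of the same libraries, a log2 difference of 3.61 (SE 0.13, adjusted p = 1.5e-56), higher in 9 of 9 libraries. H4C7.10 (Zm00001d008669) averaged 26.3 ± 9.05 against 2.81 ± 2.57, a log2 difference of 3.52. H4C7.5 (Zm00001d039733) averaged 41.4 ± 12.4 against 5.34 ± 2.91, and H3C2.6 (Zm00001d045268), the most abundant histone H3 copy, 34.8 ± 12.1 against 6.21 ± 4.09, all higher in 9 of 9 libraries. Counts of single copies are uncertain, since near-identical histone genes can share reads.

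Cluster 12 had a smaller excess of the same kind. All 23 S phase genes were higher there and all 23 adjusted over the list alone, with a median log2 difference of 0.66 (adjusted p = 1.4e-19 with the preset correlation, adjusted p = 0.0615 with an estimated correlation). H4C7 (Zm00001d027394) averaged 11.4 ± 6.93 UMIs per 10000 (SD, n = 7 libraries) against 3.92 ± 3.65, and H4C7.10 averaged 10.7 ± 4.30 against 4.36 ± 2.78. The highest named gene of cluster 12 was HMGIY2 (Zm00001d032239), which encodes a DNA-binding protein of the HMG-I/Y family, at 6.07 ± 2.45 against 2.12 ± 1.49, a log2 difference of 1.25 (SE 0.12, adjusted p = 3.3e-17). In cluster 7 all 23 S phase genes were higher as well, and in cluster 17 it was 4 of 23, or 3 adjusted over the list alone. With an estimated correlation the adjusted p was 0.234 and 0.499 in these clusters. The list was lower in 10 clusters, most fully in clusters 2 and 5, with 22 of 23 genes lower in each. Over these 10 clusters the adjusted p with an estimated correlation ran from 0.108 to 0.602.

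Aquaporins, the membrane channels for water, had their highest mean difference in cluster 13. Of the 16 tested aquaporins, 13 were higher there and none was lower, also adjusted over the list alone, with a mean log2 difference of 0.84 and a median of 0.55. The median was slightly higher in cluster 19, at 0.58. The adjusted p was 3.4e-13 with the preset correlation and 0.00601 with an estimated correlation. TIP2-1 (Zm00001d051362), a channel of the vacuolar membrane, averaged 39.7 ± 8.67 UMIs per 10000 (SD, n = 9 libraries) in cluster 13 against 8.34 ± 4.34 in the other clusters. That was a log2 difference of 3.08 (SE 0.19, adjusted p = 9.1e-32), higher in 9 of 9 libraries. TIP2-2 (Zm00001d017485) averaged 11.9 ± 8.44 against 2.99 ± 2.67, a log2 difference of 1.77. TIP2-1 was also high in cluster 19, at 34.5 ± 7.48 (n = 5 libraries), and in clusters 2 and 1, at 21.5 ± 6.29 and 20.1 ± 8.25 (n = 9 each), and its lowest mean was 0.386 ± 0.233 in cluster 15.

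In clusters 1 and 2, 11 of the 16 aquaporins were higher in each, and in cluster 19 it was 12 of 16, with an adjusted p of 0.0615 with an estimated correlation in each of these clusters. TIP2-3 (Zm00001d026177) was among those higher in cluster 2, at 5.99 ± 3.94 UMIs per 10000 (SD, n = 9 libraries) against 1.49 ± 0.659. Clusters 5, 8 and 14 passed with the preset correlation, with 6, 7 and 4 members higher and 0, 1 and 2 lower, and adjusted over the list alone 8, 7 and 3 were higher and 0, 1 and 0 lower. Their adjusted p with an estimated correlation was 0.243, 0.279 and 0.279. TIP1-1 (Zm00001d027652) had its highest mean in cluster 8, at 26.5 ± 8.66 (n = 9) against 8.88 ± 2.67, a log2 difference of 2.04 (SE 0.18, adjusted p = 2.9e-19). PIP2-6 (Zm00001d019565), a channel of the plasma membrane, was higher in clusters 8 and 11, at 6.56 ± 2.06 (n = 9) and 7.02 ± 3.02 (n = 8). NIP3-1 (Zm00001d032461) was higher in cluster 17, at 3.80 ± 1.52 (n = 8) against 0.932 ± 0.472. The aquaporin list was lower in 10 clusters, most fully in cluster 3 with 14 of 16 members lower. Over these 10 clusters the adjusted p with an estimated correlation ran from 0.0841 to 0.405.

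Ribosomal protein transcripts were highest in cluster 18 and lowest in clusters 13, 19 and 2. In cluster 18 all 8 tested ribosomal protein genes were higher, with a median log2 difference of 1.11 (adjusted p = 1.6e-04 with the preset correlation, adjusted p = 0.150 with an estimated correlation). RPL17 (Zm00001d049815) averaged 12.7 ± 2.14 UMIs per 10000 (SD, n = 5 libraries) against 4.25 ± 3.59, a log2 difference of 1.88 (SE 0.17, adjusted p = 6.8e-20). RPL30 (Zm00001d008245) averaged 15.5 ± 1.89 against 7.63 ± 1.18. RPL39 (Zm00001d018383), the most abundant member, varied most between libraries, at 18.6 ± 15.6 against 11.2 ± 13.1 in the same 5 libraries. In cluster 13 all 8 genes were lower, and in clusters 2 and 19 it was 7 of 8, or 8 adjusted over the list alone. The median log2 differences in clusters 2, 13 and 19 were -0.48, -0.73 and -0.53, and the adjusted p with an estimated correlation was 0.234, 0.191 and 0.281. Clusters 4, 11, 12 and 16 were higher with 6, 7, 5 and 7 members, and clusters 0, 6 and 17 lower with 6, 5 and 4. Their adjusted p with an estimated correlation ran from 0.118 to 0.402 and from 0.243 to 0.384.

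**Figure D2:**
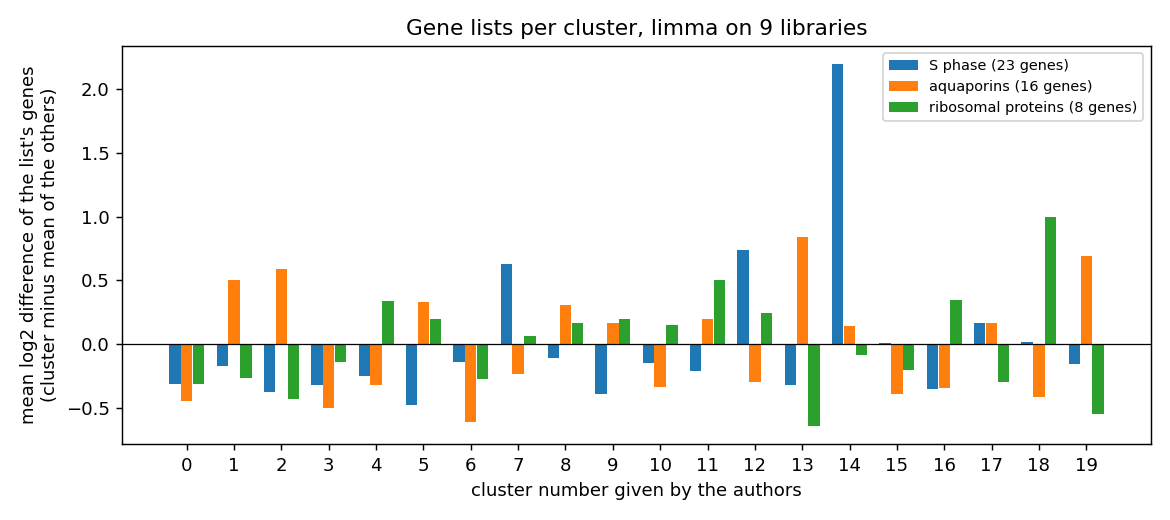
Mean log2 difference of the genes of 3 lists (vertical axis) in each of 20 clusters against the mean of the other clusters (horizontal axis), from limma on 9 libraries. The bars of the S phase list rise to 2.20 in cluster 14, those of the aquaporins to 0.84 in cluster 13, and those of the ribosomal proteins are highest in cluster 18 and fall to -0.65 in cluster 13.

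With the preset correlation 42 of the 60 list tests passed, and with an estimated correlation the S phase list in cluster 14 and the aquaporins in cluster 13 did. When cell labels were shuffled within libraries, a median of 17 and at most 28 list tests passed with the preset correlation. The test and the median and mean of the list differed in sign for the S phase list in clusters 15 and 18 and for the ribosomal proteins in cluster 7, none of which passed.

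Other named genes were higher in 1 or several clusters. CNR10 (Zm00001d012900) and its neighbour in numbering CNR9 (Zm00001d012899), of the cell number regulator family, were highest in cluster 3, at 15.7 ± 2.89 and 12.2 ± 3.04 UMIs per 10000 (SD, n = 8 libraries) against 5.01 ± 2.04 and 4.01 ± 2.00. Their log2 differences were 1.87 (SE 0.14, adjusted p = 2.7e-24) and 1.82 (SE 0.13, adjusted p = 4.2e-27). GST4 (Zm00001d024839), a glutathione S-transferase and the only named member of the list for protoplasting, wounding and heat stress, averaged 40.3 ± 10.6 in cluster 3 (n = 8) and 34.1 ± 22.0 in cluster 7 (n = 8), and was higher in all 8 libraries in both. It was also higher in clusters 13 and 2, where aquaporins were higher, with log2 differences of 1.12 and 0.94 (adjusted p = 7.3e-09 and 1.3e-06), in 9 of 9 libraries each. It passed as higher in clusters 0, 5, 10 and 17 too, and as lower in clusters 4, 8, 11, 12, 16 and 18. GLU1 (Zm00001d023994), a beta-glucosidase, was among the highest named genes of clusters 1, 2, 7, 13 and 17, with its highest mean in cluster 2 at 36.5 ± 14.4 (n = 9) against 15.3 ± 6.31. SAMDC (Zm00001d003157), which encodes S-adenosylmethionine decarboxylase of polyamine synthesis, averaged 19.4 ± 9.99 in cluster 8 (n = 9) against 7.80 ± 3.43. Zlp (Zm00001d021901) averaged 6.63 ± 4.10 in cluster 5 (n = 9) and 6.46 ± 3.41 in cluster 9 (n = 8). Within the Maize_Cell libraries alone its difference did not pass in either of these clusters. No named gene met the rule for higher genes in clusters 0, 4, 6, 10, 15 and 16. TIP2-1 was lower in each of them, by log2 differences from -1.24 in cluster 10 to -1.88 in clusters 0 and 15, with 0 of 9 libraries higher.

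SCR (Zm00001d052380), a SCARECROW gene and the only named ground tissue regulator, encodes a transcription factor that patterns ground tissue. SCR had its highest mean among the 20 tested clusters in cluster 18. It averaged 0.160 ± 0.199 UMIs per 10000 there (SD, n = 5 libraries) and 0.0409 ± 0.0713 in the other clusters. At its low level it was tested in the fit without a level filter, where the log2 difference in cluster 18 was 0.13 (SE 0.02, adjusted p = 9.9e-12), higher in 4 of 5 libraries. This SE rests on a spread shared by all clusters. Within cluster 18 the SD between libraries exceeded the mean, and the p-value does not measure that spread. In cluster 11 SCR averaged 0.0606 ± 0.0754 (n = 8), with a log2 difference of 0.03 (adjusted p = 0.0559), higher in 8 of 8 libraries. In cluster 10 it averaged 0.00368 ± 0.00893 (n = 9), with a log2 difference of -0.03 (adjusted p = 0.0452), higher in 0 of 9. Of all 1213 SCR UMIs, 900 (74.2%) came from library Maize_Cell_1, in which 22.8% of cells had a UMI. In the other libraries 0.253% to 4.37% of cells had one. Without Maize_Cell_1, SCR was higher in clusters 8, 11 and 18 (adjusted p = 4.8e-05, 2.3e-04 and 3.2e-14; in cluster 8 it was 0.391 with all libraries) and lower in clusters 3, 6 and 15 (adjusted p = 0.0339, 0.0370 and 0.0338), and cluster 10 did not pass (adjusted p = 0.0742). In cluster 15 all SCR UMIs came from Maize_Cell_1, and the 0 UMIs in 328 cells of the other 8 libraries allow up to 0.00315 UMIs per 10000 (exact Poisson limit at 95%, covering counting error only). In cluster 20, which had too few cells to be tested, SCR reached 0.184 UMIs per 10000 over all libraries (95% interval 0.136 to 0.244). Within Maize_Cell_1 it was 0.255 there (0.178 to 0.355) and 0.517 in cluster 18 (0.380 to 0.687), and in the other 8 libraries 0.105 (0.0560 to 0.180, 13 UMIs in 32 cells) and 0.0550 (0.0326 to 0.0869).

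**Figure D3:**
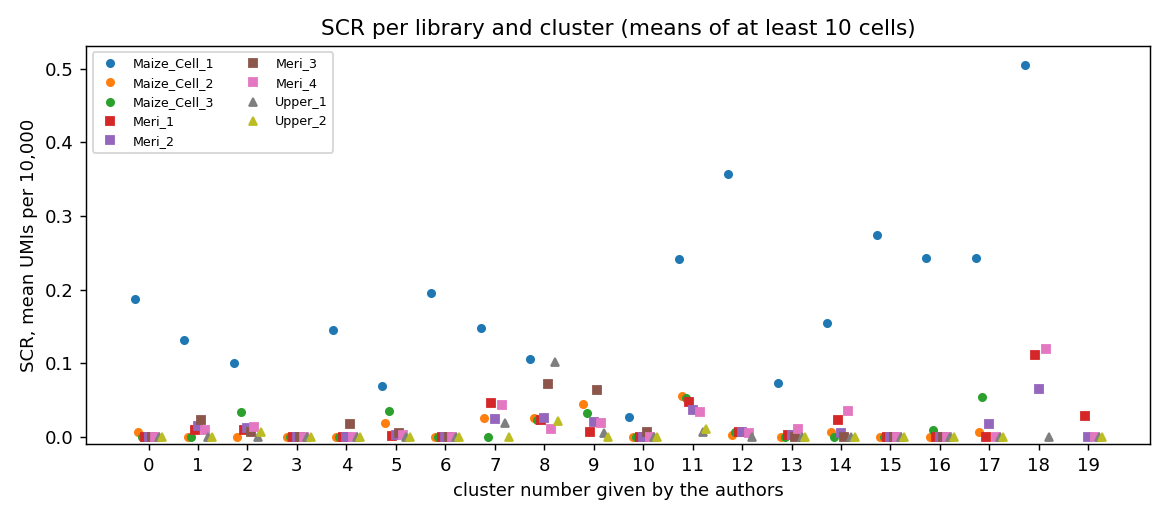
Mean SCR UMIs per 10000 (vertical axis) per library and cluster (horizontal axis), for means of at least 10 cells, with 1 point per library. The point of Maize_Cell_1 reaches 0.505 in cluster 18, where the other 4 libraries lie between 0 and 0.119.

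D8 (Zm00001d033680), a DELLA protein of gibberellin signalling and the only named member of the cytokinin and gibberellin list, was also below the level filter. Its highest means were 0.0393 ± 0.0363 UMIs per 10000 in cluster 7 (SD, n = 8 libraries) and 0.0369 ± 0.0271 in cluster 8 (n = 9). The log2 differences there were 0.02 in each (adjusted p = 0.00533 and 0.0196), higher in 5 of 8 and 7 of 9 libraries.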

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

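The tests of cluster 7 against depth, of ribosomal transcripts against all genes per library, of SCR within clusters and of gene and cluster pairs in reassigned cells were chosen after the results had been seen. The other tests were set down before their outcome was known. Of 83 groups of libraries examined for a library far from the rest, 21 had one, where chance gives about 1 in 20 for normally distributed values. That rate need not hold for SCR, which was near 0 in many libraries, and 0 in all but Maize_Cell_1 in clusters 6 and 15. Most of the 21 were SCR in Maize_Cell_1 in different clusters. These groups are not independent, so the excess over chance rests largely on a single gene in a single library.

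When cells were assigned at random to clusters of the same sizes within their library, 1 of 100 assignments, the real one included, gave as many gene and cluster pairs as the real 107967, and the highest other gave 1991. For the lists 1 of 100 gave as many calls as the real 42, and the highest other gave 28. Since the authors built the clusters from these same cells, these comparisons alone could not exclude chance. Cells were therefore assigned from one part of their UMIs and measured in the other. That gave 97007 pairs and 49 list calls, also above the highest random assignment, so random labels are excluded as the source of these counts. Random labels also remove differences in UMIs per cell between clusters, and the profiles came from clusters built on all UMIs. The comparison therefore cannot tell these clusters from another grouping of cells, such as one by depth. Chance is not excluded for single list calls with the preset correlation.

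Cluster 7 held 26.1% of the cells of library Maize_Cell_1 and 0.779% to 5.45% of those of the other libraries. Shallow sequencing is argued against by Maize_Cell_3, which had a lower median depth (8347 against 14814 UMIs per cell) and 2.21% of its cells in cluster 7. A shift of that library, which would move cells of other clusters into cluster 7, remained open. When cells were reassigned with profiles from the other libraries, 48.0% of the cluster 7 cells of Maize_Cell_1 stayed there, against 39.2% in the other libraries together, and 31.9% of them went to cluster 17. The light regime and kit of the samples could not be tied to the library names, so no biological explanation was tested.

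SCR UMIs came mostly from Maize_Cell_1, which lay apart from the other libraries in 15 clusters. Its values there were 0.187 UMIs per 10000 in cluster 0, 0.132 in 1, 0.0999 in 2, 0.145 in 4, 0.195 in 6, 0.148 in 7, 0.0268 in 10 (a single UMI in 11 cells) and 0.242 in 11, and in clusters 12 to 18 they were 0.357, 0.0730, 0.155, 0.274, 0.242, 0.243 and 0.505. Other gene models behind the matrix than behind the counts table are argued against, since the counts table held 66.6% of that library's SCR UMIs, within the 60 to 85 percent set in advance. That ratio compares the library with itself and cannot show a difference in gene models between libraries. In the counts table Maize_Cell_1 had UMIs in 0 of the rows with a symbol, SCR's among them, whereas Maize_Cell_2 and Maize_Cell_3 had UMIs in 179 and 166 of them. Gene models shared by both tables stay open, and so do more cells rich in SCR: Maize_Cell_1 lay above the range of the other libraries in 17 of 17 clusters compared, but RNA from outside the cells would raise SCR in every cluster and was not measured. A difference of the library that acts on few genes is not excluded either. Among 16520 genes compared, a wider set than the genes tested, 17 were 8 times higher in Maize_Cell_1 than in any other library (at most 3 elsewhere). SCR was itself 1 of the 17. By the rule set in advance, fewer than 20 counted against this explanation. The shortfall was less than the counting error of such a number, a margin that the rule did not include. The result thus went against the explanation by that rule, but too narrowly to exclude it. Another 74 genes were 8 times lower in Maize_Cell_1 (at most 13 elsewhere), and no biological explanation was tested.

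Ribosomal protein genes were lower in clusters 2, 13 and 19, 3 of the 7 clusters where aquaporins were higher. In the other 4 (1, 5, 8 and 14) the ribosomal list did not pass. Of its 8 members, 5 were lower in cluster 1 and 2 in cluster 14, and 2 were higher in cluster 5 and 3 in cluster 8. With cells reassigned to clusters the list test (camera, preset correlation) passed as higher in clusters 5 and 8 (adjusted p = 0.00345 and 0.00279). Both lists were lower in clusters 0 and 6. Abundant transcripts that take a share of all other genes' UMIs would lower all genes by the same fold. On summed UMIs, though, the ribosomal median fell below that of all genes by a mean log2 of -0.72 in cluster 2 (95% interval -0.92 to -0.51, n = 9 libraries), -1.26 in cluster 13 (n = 9) and -1.47 in cluster 19 (n = 5), which argues against that explanation. An effect of UMIs per cell through the mean of log values is argued against by edgeR on summed UMIs, where the same differences were -0.62, -0.83 and -1.23. A biological reason in these 3 clusters stays a hypothesis, found and tested on the same data. With an estimated correlation the ribosomal list did not pass in any of them, and the aquaporin list passed in cluster 13 alone.

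Other values stood apart without further weighing. Cluster 15 held 8.20% of the cells of Meri_3, against 1.41% to 4.75% in the other libraries. Cluster 18 held 1.54% of the cells of Maize_Cell_1, against 0.282% to 0.861% in the others. Cluster 20 held 3.08% of the cells of Maize_Cell_1, against 0% to 0.814% in the others. TIP2-3 averaged 15.2 UMIs per 10000 in cluster 2 in Maize_Cell_2, against 0.578 to 6.69 in the others. SCR averaged 0.0280 in cluster 19 in Meri_1 and 0 in the other 4 libraries. In the clusters left out of the tests for want of cells, TUBA3 reached 9.65 UMIs per 10000 in cluster 20 (exact Poisson interval 9.28 to 10.0; 7.03 in Maize_Cell_1 alone) and TIP2-2 reached 23.4 in cluster 21 (21.6 to 25.4).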

How the results depend on the processing

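Fits within each name family of libraries, edgeR with TMM, the deposited counts, genes and lists with cells reassigned to clusters, lists without Maize_Cell_1 and SCR without each library were chosen after seeing the data. The 2040 pairs with a log2 difference of at least 1 in either direction all stayed called when any 1 library was left out, and between 92.3% and 100% of those that could be compared stayed called under every other alternative. Counts of all pairs depended more on the setting. Against 50708 higher and 57259 lower pairs, the fit with no replicate block gave 28875 and 26622, and the Maize_Cell libraries alone gave 18789 and 14987. Higher pairs numbered 94945 in edgeR with TMM, 94013 in edgeR with DESeq2 size factors and 93858 in DESeq2, which also tested 18331 genes in place of 12776. The deposited counts of 3 libraries gave 15977 lower pairs. Without 1 library at a time, 43942 to 51724 pairs were higher and 46401 to 59946 lower. Values from reassigned cells gave 47018 and 49989, and 99.6% of the large differences stayed called. The share of higher calls moved from 47.0% to 59.9% with TMM, 58.8% with DESeq2 size factors and 69.2% with the deposited counts. The cause was not tested.

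With an estimated correlation the S phase list was higher in 1 cluster in place of 4 and lower in 0 in place of 10. Aquaporins were higher in 1 in place of 7 and lower in 0 in place of 10, and ribosomal proteins higher in 0 in place of 5 and lower in 0 in place of 6. The estimated correlations, 0.59, 0.24 and 0.41, lie above the preset 0.01. With cells reassigned to clusters 39 of the 42 list calls stayed, in the same direction. The S phase calls in clusters 10, 13 and 17 were lost (adjusted p = 0.641, 0.130 and 0.497). Newly called were S phase in clusters 1, 6, 8 and 15 (lower) and 18 (higher), and ribosomal proteins in clusters 5, 8, 9 and 10 (higher, making 9 clusters in place of 5) and 15 (lower). Without Maize_Cell_1, 55 of 60 list tests kept their side of the threshold and 5 passed that had not. Of 854 values of named genes under alternatives, 842 kept their direction and side of the threshold, 10 fell short of it and 2 newly passed, and none changed direction. Those that fell short were Zlp in clusters 5 and 9 and SCR in cluster 10. SCR in clusters 10, 11 and 18 was followed because of its values; its log2 difference ran from -0.04 to -0.01, 0.03 to 0.04 and 0.08 to 0.16 without 1 library at a time. In cluster 10 it passed only with all libraries or without Upper_1 (adjusted p = 0.0271), and in cluster 11 only without Maize_Cell_1 (adjusted p = 2.3e-04) or Upper_1 (adjusted p = 0.0430). In cluster 8 it passed only without Maize_Cell_1 (adjusted p = 4.8e-05, against 0.391 with all libraries and 0.868 without Upper_1, which had 16 cells there). Leaving out Maize_Cell_1 lowered the mean share of cluster 7 from 4.74% to 2.06% and that of cluster 20 from 0.592% to 0.280%; no other mean share moved by over 1.5 times.

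Fits of 1 light regime or kit were not run, because libraries could not be tied to samples. The 3 contrasts of named tissues had no cell type names to run on. The filter at 1000 UMIs per cell removed 0 cells. Lists without description matches were the lists used, since no descriptions were given. The alternatives planned for data without a library map did not apply. Clusters 3, 6, 15 and 21 had 0 SCR UMIs from the other 8 libraries together, and clusters 4, 10, 16 and 19 had 1 each.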

Other observations

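Further named genes, chosen after their values were seen, had their highest mean among the tested clusters as follows. PIP2-4, an aquaporin of the plasma membrane, averaged 3.86 ± 2.87 UMIs per 10000 in cluster 13 (SD, n = 9 libraries), a log2 difference of 1.44 (SE 0.10, adjusted p = 8.7e-27). CNR7 averaged 1.58 ± 1.52 in cluster 7 (n = 8), a log2 difference of 0.81 (SE 0.07, adjusted p = 3.8e-20), and CNR2 averaged 2.33 ± 2.73 in cluster 15 (n = 9), a log2 difference of 0.62 (SE 0.09, adjusted p = 9.6e-10). Both varied widely between libraries, a spread within the cluster that these p-values do not measure. In Maize_Cell_1, which held 627 of the 844 cells of cluster 7, CNR7 reached at most 0.212 in any tested cluster. CNR2 reached at most 0.285 in that library. CNR7 and CNR2 share the cell number regulator name with CNR9 and CNR10, which were highest in cluster 3. In cluster 18 the chaperonin genes CPN60I and CPN60II averaged 1.32 ± 0.358 and 1.35 ± 0.524 (n = 5), with log2 differences of 0.92 (SE 0.05) and 0.86 (SE 0.06). PCNA had its highest mean in cluster 18 as well, at 0.979 ± 0.264 (n = 5), a log2 difference of 0.50 (SE 0.06, adjusted p = 2.1e-14). It averaged 0.778 ± 0.259 in cluster 12 (n = 7) and 0.505 ± 0.330 in cluster 14 (n = 9), whereas the histone H4 copy H4C7.2 averaged 31.5 ± 19.7 in cluster 14.

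Clusters 20 and 21 held 106 and 17 cells and were not tested. Their values are sums over cells, with exact Poisson intervals that cover counting error only. Of the 106 cells of cluster 20, 74 came from Maize_Cell_1, so its levels were compared within that library. There TUBA3, an alpha tubulin, reached 7.03 UMIs per 10000 (6.60 to 7.49) in cluster 20, against a mean of 3.74 and at most 5.38 in the library's 17 tested clusters. CPN60I at 0.904 (0.752 to 1.08) and RPL17 at 13.9 (13.3 to 14.6) lay above the library's means of 0.577 and 10.9 but below its highest tested cluster, and RPS21 at 6.04 (5.64 to 6.47) lay close to its mean of 5.79. The 17 cells of cluster 21 all came from Meri and Upper libraries, and their levels were not compared within these libraries. They included TIP2-2 at 23.4 UMIs per 10000 (21.6 to 25.4), PIP2-5 at 3.32 (2.66 to 4.10), DER1.1 at 2.52 (1.95 to 3.21), PIP2-6 at 13.9 (12.5 to 15.4) and Zlp at 16.8 (15.2 to 18.4).

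Transcripts of the mitochondrial genome made up 0.147% ± 0.0434 of UMIs in cluster 5 (SD, n = 6 libraries), the lowest mean, and 0.326% ± 0.0580 in cluster 18 (n = 4), the highest. Those of the plastid genome made up 0.0338% ± 0.00449 in cluster 19 (n = 5) and 0.127% ± 0.0306 in cluster 18 (n = 4). Both were measured in the Meri and Upper libraries, which use the organelle locus tags. Over all cells of a library the mitochondrial share was 0.445% in Meri_3 and 0.138% to 0.306% in the other 5.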
